A study of Arabidopsis thaliana with 18 samples.

How the data were processed

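The series holds 18 libraries of 10-day-old Arabidopsis thaliana seedlings of ecotype C24, WT or pold2 by the labels. The submitters' processing notes name Bowtie 0.12.9, SAMtools, TopHat2 2.1.1, Cuffdiff 2.1.1, bcl2fastq, Bismark 0.7.4 and Bowtie2 2.0.5 and the TAIR10 build, with no role or order. The RNA table gives FPKM values that the authors pooled to 1 per genotype, per the file headers, from 3 libraries per genotype, per the labels. The log2 fold change in the authors' deposited table is that of pold2 over WT, per the file headers. The p-value and q-value columns of the authors' deposited table were used as they stand. The deposited q values equal the Benjamini-Hochberg adjustment of the deposited p values over all 19858 genes, checked to within 5.28e-07. The smallest p is 5e-05, shared by 965 genes, so that many genes share the smallest q of 0.00103 and cannot be ranked by it. Every listed gene has at least 0.501 FPKM in one of the genotypes, so the lowest genes are outside the table. Recomputed log2 ratios matched the deposited ones to within 0.001 in all rows with 2 finite values but 1. Pooling hides the spread between libraries, and FPKM without counts leaves the depth unknown, so no error of a single gene could be computed.

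The peak lists give a start, an end and a score per peak as the authors deposited them, with peak names that begin with MACS, per the files. The version of the caller and the control used are not given in the sources used here. Scores start at 50.0 and reach 3233. They are the authors' values, and were used only to rank peaks within a list. Each list comes from 1 WT library, so a peak has no replicate.

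No test across libraries was possible with 1 value per genotype, so genes were called at the authors' q under 0.05, the case written into the design before the data were examined for a table of this kind. Gene symbols and types came from a reference gene table of assembly TAIR10.1, which matched 19812 of 19858 identifiers, and none of its coordinates was used. Gene coordinates are those of the loci in the authors' deposited table, in TAIR10 and counted from 1. These loci are merged where genes overlap, and 2820 genes share a locus with another gene. They carry no strand. A gene was called marked where a peak covered at least 1 bp of its locus, or for H3K4me3 at least 1 bp of the locus and 500 bp on both sides. The plan had named the 500 bp upstream only for H3K4me3, which needs a strand.

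Lists of genes (21 lists, 373 entries) were written before the data were examined. They cover the damage response, repair, replication, G2/M, S-phase histones, flowering, silencing, telomeres, tissues and stress. The median log2 ratio of each list was ranked among 10000 random lists matched in 20 bins of mean expression. A list needed 3 listed genes. Transposable element genes were taken to be the 41 identifiers with a transcript suffix, since the table names no such class. Shares were compared with Fisher's exact test, two-sided, with Wilson intervals at 95% and Benjamini-Hochberg adjustment over the 6 tests of marks and directions. Matched draws took unmarked genes with replacement in the same 20 bins, 10000 times. Mean expression is the mean of the WT and pold2 FPKM, so a gene's own change can move its bin. Peak lists were compared by the bases they share, against 1000 circular shifts, and WT medians against 10000 permutations of gene labels.

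The genes named were POLD2 first. Then came the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 FPKM, up to 4 called members of each list by smallest q with ties by size of change, or the 2 most expressed members where none was called. They were followed by 3 transposable element genes and the 5 largest rises under H3K27me3. A gene with a genotype listed at 0 has no fold.

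The list percentiles, the tests of changed genes among marked genes and the overlap of peak lists were tested on simulated data, and the other steps were not. The simulated lists were drawn at random from 19841 genes, so these runs do not cover genes that vary together. With no shift such lists fell outside the middle 95% in 4% (10 genes) and 3% (20 genes) of 100 runs. With a log2 shift of 0.2 they were called in 68% and 91%, and with 0.4 in 99% and 100%. For changed genes among marked genes, 200 calls placed among 19858 genes at odds of 1, 2 and 4 were called in 1%, 99% and 100% of 100 runs. These runs used the 3033 genes with H3K27me3 only, so they do not cover the 135 genes with H3K9me2. For the overlap of peak lists of 2000 peaks, 5% of 20 runs were called with no shared peaks and 100% with a planted share of 0.2. Those peaks were scattered evenly, and only an excess of shared bases was tested. The runs therefore do not cover a deficit of shared bases or peaks that cluster.

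Alternatives were another expression minimum (5 FPKM), a stricter q (0.01), a 2-fold minimum, median-ratio scaling, pseudocounts of 0.1 and 5, the better-scoring 50% of each peak list, and a peak over 50% of the locus or 200 bp for H3K4me3. Others were added after the data were seen and are named as such. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The bisulfite libraries, the pold2 ChIP libraries and the H3 and input libraries were not analysed here.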

Results

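RNA, histone marks and DNA methylation were profiled in whole seedlings of Arabidopsis thaliana, ecotype C24, to compare wild type (WT) with the pold2 mutant. POLD2 is the second subunit of DNA polymerase delta, one of the polymerases that copy the genome. The seedlings were 10 days old and grew on sucrose medium at 22°C with 23 h of light per day. The series holds 18 libraries. Of these, 6 were RNA-seq libraries (3 per genotype), 2 were bisulfite libraries (1 per genotype) and 10 were chromatin immunoprecipitation (ChIP) and input libraries (1 per genotype for H3K27me3, H3K4me3, H3K9me2, H3 and input). The RNA data were analysed from the authors' deposited table, which gives 1 pooled FPKM value per genotype for each of 19858 genes with the authors' fold change, p and q. The ChIP data were analysed from the WT peak lists of 3 marks, each from 1 library. The bisulfite libraries, the pold2 ChIP libraries and the H3 and input libraries were not analysed here. No value per library was used, so the RNA values have no SD or n. Read depth is unknown, and the labels do not say whether the RNA libraries came from separate cultures, so the authors' q values may measure technical spread only.

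The first comparison asked which genes changed their transcript level in pold2. The targeted gene itself, POLD2 (AT2G42120, chromosome 2, 17563157 to 17566032, TAIR10), stood at 7.21 FPKM in WT and 2.83 FPKM in pold2 in the authors' deposited table, which is 2.55-fold lower (q = 0.00103). By the authors' deposited table, 2470 of the 19858 genes (12.4%) had a q under 0.05, of which 1185 were higher and 1285 lower in pold2. Changes of at least 2-fold were mostly increases, with 239 genes higher and 77 lower in the authors' deposited table. At an unadjusted p under 0.05 the authors' deposited table held 4764 genes, where chance alone gives 993. The median log2 ratio of all genes was -0.01, so a median-ratio scaling hardly moved the values.

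Regulators of flower identity led the increases. Among called genes with a mean of at least 1 FPKM, the 10 largest rises in the authors' deposited table included 5 MADS-box genes that specify floral organs. They were SEP2 (AT3G02310, 75.7-fold), AP3 (AT3G54340, 41.0-fold), SEP3 (AT1G24260, 28.8-fold), SEP1 (AT5G15800, 17.5-fold) and PI (AT5G20240, 16.7-fold) in the authors' deposited table. SEP3, on chromosome 1 from 8593637 to 8596105, went from 6.79 FPKM in WT to 196 FPKM in pold2 in the authors' deposited table. AT3G49270 (chromosome 3, 18267252 to 18268271) was listed at 0 in WT and at 8.52 FPKM in pold2 in the authors' deposited table. The other rises among the 10 in the authors' deposited table were AT3G28500 (21.8-fold), VIM5 (AT1G57800, 19.5-fold), the sugar transporter gene SWEET10 (AT5G50790, 11.5-fold) and AT1G11070 (10.7-fold). SEP2, AP3, SEP1, PI, VIM5 and SWEET10 were each under 0.5 FPKM in WT in that table, which makes their folds uncertain. Of these 10 genes, 9 carried an H3K27me3 peak in WT, and AT1G11070 did not.

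The largest fall among called genes with a mean of at least 1 FPKM in the authors' deposited table was that of AT2G09795, a long noncoding RNA gene on chromosome 2 (3667253 to 3672729), from 9.15 to 0.201 FPKM (45.5-fold lower, q = 0.0385). AT5G46960 followed at 6.63-fold lower, then RL6 (AT1G75250), a gene for a MYB-type protein, at 4.99-fold lower in the authors' deposited table. MRU1 (AT5G35490) was 4.59-fold lower and AT1G14250 4.42-fold lower in the authors' deposited table. The remaining falls among the 10, at 3.41-fold to 3.92-fold lower in the authors' deposited table, were those of AT3G16120, AT2G32550, AT3G58000, AT1G29090 and AT3G62950. All 10 genes were under 10 FPKM in WT. RL6, MRU1 and AT3G16120 carried no H3K27me3 peak in WT, and the others among the 10 did.

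Gene lists fixed before the data were examined were then compared between the genotypes. For each list the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, which describes these pooled values and is no test across replicates. Of 20 lists with a percentile, 10 lay outside the middle 95%, where lists of genes that vary independently would give 1. Members of a list can vary together, which the random lists do not imitate, so more than 1 could lie outside without an effect of genotype. Members missing from the table are left out, which removes genes that stayed silent in both genotypes.

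Genes of the DNA damage response rose together. Of 22 listed genes, 18 were called higher and 0 lower in the authors' deposited table (19 higher when adjusted over the list alone), and the median log2 ratio was 1.25, at percentile 100. SMR7 (AT3G27630), a cyclin-dependent kinase inhibitor induced by DNA damage, went from 24.7 to 131 FPKM in the authors' deposited table (5.31-fold, q = 0.00103). The homologous recombination gene BRCA1 (AT4G21070) was 3.84-fold higher, the transcription factor gene NAC044 (AT3G01600) 3.32-fold and the thymidine kinase gene TK1A (AT3G07800) 2.84-fold in the authors' deposited table. Of the 31 recombination and repair genes, 1 was called, WEE1 (AT1G02970, 1.59-fold higher), in the authors' deposited table. Adjusted over the list alone it was also 1, and the list's median log2 ratio was 0.04, at percentile 72.0.

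Of 34 genes of the replication machinery, 3 were higher and 4 lower in the authors' deposited table (4 and 4 adjusted over the list alone), with a median log2 ratio of -0.05, at percentile 14.3. POLD2 was among the lower ones, with MCM6 (AT5G44635, 1.299-fold lower), part of the replicative helicase, in the authors' deposited table. POL2A (AT1G08260), the catalytic subunit of DNA polymerase epsilon, was 1.57-fold higher, and the ribonucleotide reductase gene RNR1 (AT2G21790) was 1.39-fold higher in the authors' deposited table. Of 22 genes of the G2/M phase, 4 were higher and 0 lower in the authors' deposited table (5 higher adjusted over the list alone), with a median log2 ratio of 0.08, at percentile 97.3 (99.8 among genes with a mean of at least 5 FPKM, a setting added after the data were seen). The 4 were CYCB1;1 (AT4G37490, 1.80-fold), CDKB1;1 (AT3G54180, 1.47-fold), CDC20.2 (AT4G33260, 1.29-fold) and CDKB2;1 (AT1G76540, 1.26-fold) in the authors' deposited table. CYCB1;1 is also a member of the damage response list.

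Histone genes expressed in S phase fell. Of 13 genes for histones H3.1 and H4, 11 were called lower and 0 higher in the authors' deposited table (13 lower adjusted over the list alone), and the median log2 ratio of -0.48 lay at percentile 0 of the matched lists. An H3.1 gene, AT3G27360, went from 94.7 to 50.7 FPKM (1.87-fold lower), and an H4 gene, AT3G45930, from 192 to 118 FPKM (1.63-fold lower), in the authors' deposited table. These genes are nearly identical in sequence, so the split of reads among them is uncertain.

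The medians of the flowering lists moved in opposite directions by class. Of 10 listed activators of flowering, 4 were higher and 0 lower in the authors' deposited table (5 higher adjusted over the list alone), with a median log2 ratio of 0.59, at percentile 99.8. AGL24 (AT4G24540) was 3.87-fold higher, SOC1 (AT2G45660) 3.60-fold and FT (AT1G65480), which encodes the mobile flowering signal, 3.19-fold in the authors' deposited table. FT was at 0.495 FPKM in WT in that table, which makes its fold uncertain. AP1 (AT1G69120) was listed at 0 in WT and at 0.813 FPKM in pold2 in the authors' deposited table. Among genes with a mean of at least 5 FPKM, a setting added after the data were seen, the activators' percentile was 94.3. Of 12 repressors of flowering, 7 were lower and 0 higher in the authors' deposited table (8 lower and 1 higher adjusted over the list alone), with a median log2 ratio of -0.48, at percentile 0.01. FLC (AT5G10140, chromosome 5, 3173497 to 3179448), the repressor that vernalization silences, fell from 114 to 74.1 FPKM in the authors' deposited table (1.54-fold lower). Its relative MAF4 (AT5G65070) was 2.36-fold lower, TOE1 (AT2G28550) 1.47-fold lower and TEM2 (AT1G68840) 1.46-fold lower in the authors' deposited table. The MAF genes are similar enough to share reads. Of 16 floral homeotic and meristem regulators, 8 were higher and 0 lower in the authors' deposited table (8 higher adjusted over the list alone), with a median log2 ratio of 2.80, at percentile 100. That median lies between 2 uncalled genes near 0 in WT and shrank to 1.94 with pseudocount 0.1 and to 0.71 with pseudocount 1 (added after the data were seen), both still at percentile 100. Besides SEP1, SEP3 and PI, the rule named SEP4 (AT2G03710), at 1.73-fold higher in the authors' deposited table. All 16 carried an H3K27me3 peak in WT. Such a peak was also common in lists whose median did not rise, at 14 of 16 root markers and 8 of 12 jasmonate and wounding genes.

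Genes of the silencing machinery were compared next. None of 15 Polycomb and Trithorax genes was called in the authors' deposited table (0 adjusted over the list alone), with a median log2 ratio of -0.02, at percentile 42.4. At an unadjusted p under 0.05, 2 of the 15 passed in that table. SWN (AT4G02020), a histone methyltransferase of Polycomb, was at 29.7 FPKM in WT and 34.2 FPKM in pold2 in the authors' deposited table. MSI1 (AT5G58230) was at 31.0 FPKM in WT and 30.3 FPKM in pold2 in that table. Of 36 genes of DNA methylation and silencing, 5 were higher and 1 lower in the authors' deposited table (7 and 2 adjusted over the list alone), with a median log2 ratio of 0.12, at percentile 99.7. MET1 (AT5G49160), which maintains CG methylation, was 1.27-fold higher, the histone demethylase gene IBM1 (AT3G07610) 1.29-fold higher and AGO9 (AT5G21150) 2.63-fold higher in the authors' deposited table. AGO9 was at 0.267 FPKM in WT in that table, which makes its fold uncertain. CMT2 (AT4G19020), a non-CG methyltransferase, was 1.31-fold lower in the authors' deposited table. Of 7 loci known to be kept silent by DNA methylation, 1 was listed, SDC (AT2G17690), at 0.850 FPKM in WT and 0.286 FPKM in pold2 in the authors' deposited table (q = 0.0298, also called adjusted over the list alone). None of 8 telomere genes was called in the authors' deposited table (0 adjusted over the list alone), with 2 at an unadjusted p under 0.05, a median log2 ratio of -0.07 and percentile 20.6. TRP1 (AT5G59430) was at 35.5 FPKM in WT and 31.6 FPKM in pold2, and TRB1 (AT1G49950) at 23.0 and 21.4 FPKM, in the authors' deposited table.

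Transposable element genes were also compared, since the study measured DNA methylation and H3K9me2, which silence them. The 41 entries listed by a transcript identifier were taken as this set, and 39 of them are pseudogenes in the reference gene table. By symbol, 6 of the 41 are MUSTANG genes and 4 Sadhu elements. Whether DNA methylation or H3K9me2 silences these 41 entries was not tested. Of these 41, 3 were higher (7.32%, against 5.96% of the 19817 others) and 0 lower (against 6.48%) in the authors' deposited table. Fisher's exact test separated neither the higher genes (two-sided p = 0.735) nor the lower genes (p = 0.111), nor both together (7.32% against 12.4%, p = 0.475). The 3 were AT1G61510.1 (3.11-fold), AT4G22450.1 (2.14-fold) and AT3G50625.1 (1.60-fold, from 0.432 FPKM in WT, so less certain) in the authors' deposited table. AT1G61510.1 and AT4G22450.1 lay under both an H3K27me3 and an H3K9me2 peak in WT, and AT3G50625.1 under an H3K27me3 peak. With 41 entries above the table's expression minimum, most transposons were outside this comparison.

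Some of the lists of tissue markers and of genes that answer growth conditions moved. Of 21 photosynthesis genes, 12 were lower and 0 higher in the authors' deposited table (14 lower and 1 higher adjusted over the list alone), with a median log2 ratio of -0.33, at percentile 0.02. LHCA1 (AT3G54890), a light-harvesting protein of photosystem I, went from 4782 to 2906 FPKM in the authors' deposited table (1.65-fold lower). LHCB1.1 (AT1G29920) was 1.49-fold lower, LHCB2.2 (AT2G05070) 1.44-fold lower and LHCB2.1 (AT2G05100) 1.41-fold lower in the authors' deposited table, with reads that similar copies can share. Of 16 root markers, 1 was called, the iron transporter gene IRT1 (AT4G19690, 1.44-fold higher), in the authors' deposited table (1 adjusted over the list alone). The root list had a median log2 ratio of -0.09, at percentile 8.01. Of 8 listed seed maturation genes, 5 were higher and 0 lower in the authors' deposited table (6 higher adjusted over the list alone), with a median log2 ratio of 1.24, at percentile 100. The storage protein genes CRC (AT4G28520) and CRA1 (AT5G44120) were 10.1-fold and 4.41-fold higher, and the oleosin genes OLEO2 (AT5G40420) and OLEO4 (AT3G27660) 2.58-fold and 2.16-fold higher, in the authors' deposited table. All 8 carried an H3K27me3 peak in WT, as did 14 of the 16 root markers, of which 1 was called.

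Of 15 salicylate and defence genes, 7 were higher, 0 lower and 8 not called in the authors' deposited table (7 higher adjusted over the list alone), with a median log2 ratio of 0.48, at percentile 100. PBS3 (AT5G13320) was 2.12-fold higher, PAD3 (AT3G26830) 1.49-fold, PR1 (AT2G14610) 1.45-fold and WRKY70 (AT3G56400) 1.40-fold in the authors' deposited table. Of 12 jasmonate and wounding genes, 2 were higher and 2 lower in the authors' deposited table (2 and 2 adjusted over the list alone), with a median log2 ratio of -0.12, at percentile 4.50 (1.94 with pseudocount 1, added after the data were seen), and a mean of 0.45. VSP2 (AT5G24770) was 9.94-fold and VSP1 (AT5G24780) 3.58-fold higher, while the jasmonate synthesis genes AOC2 (AT3G25770) and AOC1 (AT3G25760) were 2.01-fold and 1.32-fold lower, in the authors' deposited table. VSP2 and VSP1 were at 0.180 and 0.438 FPKM in WT in that table, which makes their folds and the list's mean uncertain. Of 11 anthocyanin and flavonoid genes, 3 were lower and 0 higher in the authors' deposited table (3 lower adjusted over the list alone), with a median log2 ratio of -0.25, at percentile 0.15. They were DFR (AT5G42800, 1.74-fold lower), LDOX (AT4G22880, 1.68-fold lower) and TT19 (AT5G17220, 1.65-fold lower) in the authors' deposited table. Among genes with a mean of at least 5 FPKM this list stood at percentile 17.63. Of 6 heat shock genes, HSP101 (AT1G74310) was 1.40-fold higher and HSP18.2 (AT5G59720) 1.73-fold lower in the authors' deposited table (1 and 1 adjusted over the list alone), with a median log2 ratio of 0.25, at percentile 93.1. Of 13 cold and abscisic acid genes, RD29B (AT5G52300) was 1.61-fold higher, and KIN1 (AT5G15960) and ADH1 (AT1G77120) were 1.94-fold and 1.48-fold lower, in the authors' deposited table (1 and 3 adjusted over the list alone). That list had a median log2 ratio of -0.05, at percentile 41.3. None of 10 circadian clock genes was called in the authors' deposited table (0 adjusted over the list alone), with 3 at an unadjusted p under 0.05, and a median log2 ratio of -0.10, at percentile 10.5. LHY (AT1G01060) was at 111 FPKM in WT and 114 FPKM in pold2, and CCA1 (AT2G46830) at 77.7 and 70.2 FPKM, in the authors' deposited table. Of the genes named so far, SEP1, POL2A, CDKB2;1, the H3.1 gene AT3G27360, MSI1, HSP101, ADH1 and AT1G61510.1 share a locus with another gene in the table, so their values are less certain.

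**Figure D1:**
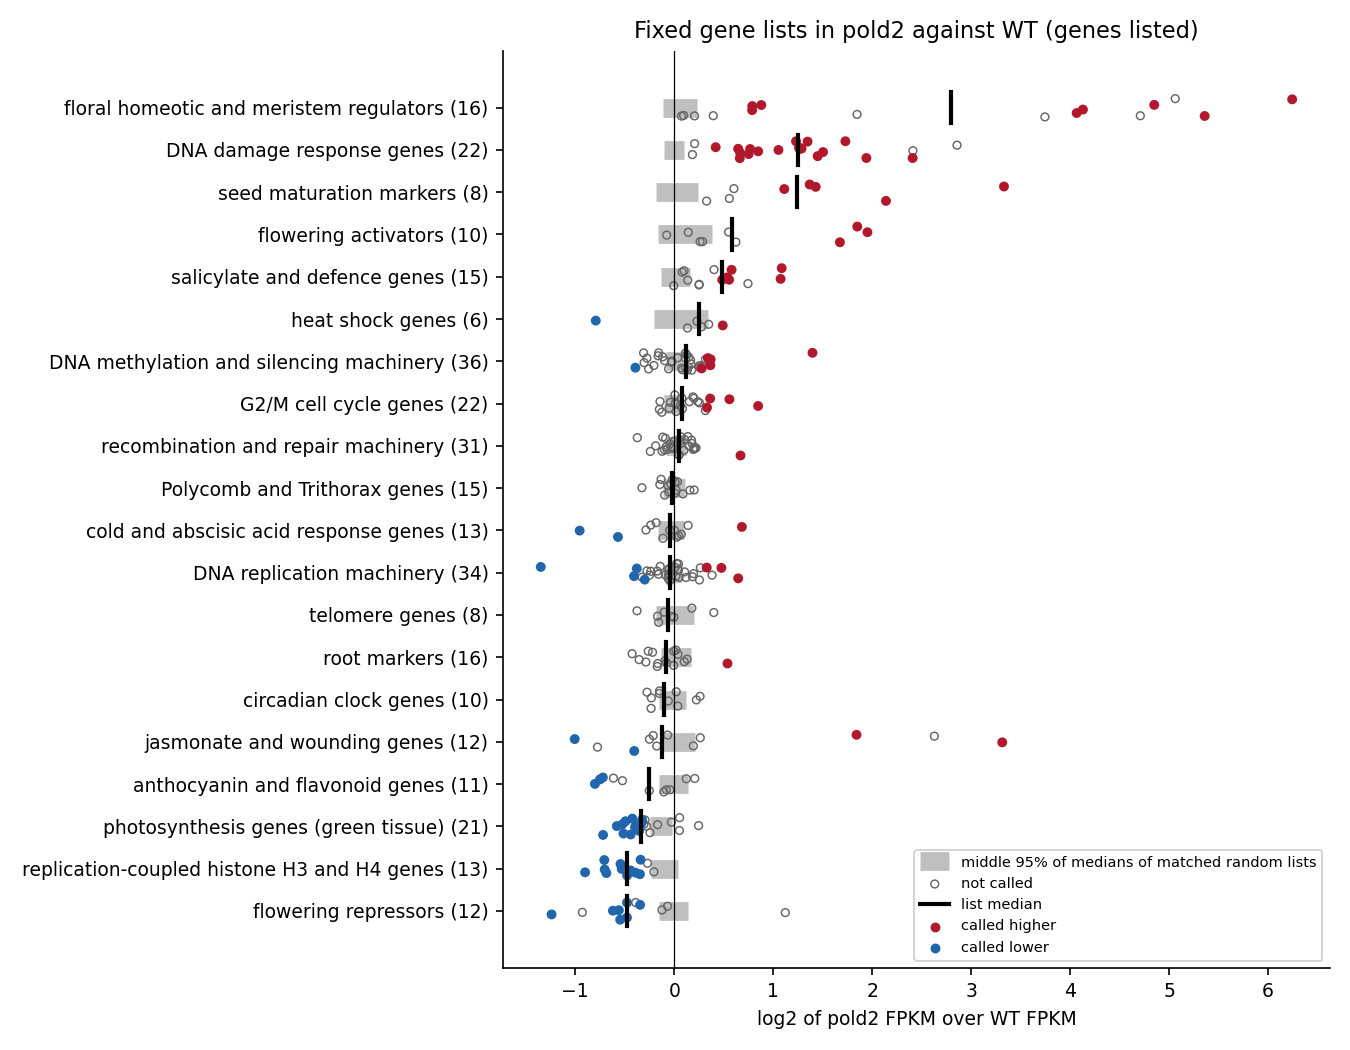
The log2 ratio of pold2 over WT FPKM is plotted for each listed gene of the 20 lists with a percentile, with filled points for genes the authors' deposited table calls at q under 0.05, a black bar at the list median and a grey band for the middle 95% of medians of matched random lists. Genes with a genotype listed at 0 are left out of the points. Without a pseudocount the floral regulators have the highest median (2.80), which rests on genes near 0 in WT, and the flowering repressors and S-phase histone genes the lowest (-0.48 each).

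The WT peak lists show where each mark lay. H3K27me3, the mark of Polycomb repression, had 7271 peaks, and its nuclear peaks had a median length of 1859 bp and covered 16.3 Mb (13.7% of the span of the 5 chromosomes). H3K4me3, found at the start of transcribed genes, had 15782 peaks, of which the 15724 nuclear ones covered 22.8 Mb (19.1%). H3K9me2, a mark of silent heterochromatin, had 8461 peaks, of which the 8394 nuclear ones covered 12.4 Mb (10.4%). Of the 19858 listed genes, 3033 (15.3%) carried H3K27me3, 17159 (86.4%) H3K4me3 and 135 (0.680%) H3K9me2. H3K9me2 was concentrated around the centromeres. It covered 70.1% of the window from 12 to 13 Mb on chromosome 5, 69.6% of the same window on chromosome 3, 59.5% from 15 to 16 Mb on chromosome 1, 54.8% from 4 to 5 Mb on chromosome 2 and 48.5% from 3 to 4 Mb on chromosome 4. Inside the H3K9me2-rich part of chromosome 2 lay a stretch dense in H3K4me3 peaks, from 3247180 to 3509666, with 73.8% of its bases under H3K4me3 and 0.190% under H3K9me2. These peaks had a median score of 202, against 1527 for other nuclear H3K4me3 peaks. Reads of mitochondrial DNA were not excluded as their source. Each mark came from 1 library, so these values have no replicate check.

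**Figure D2:**
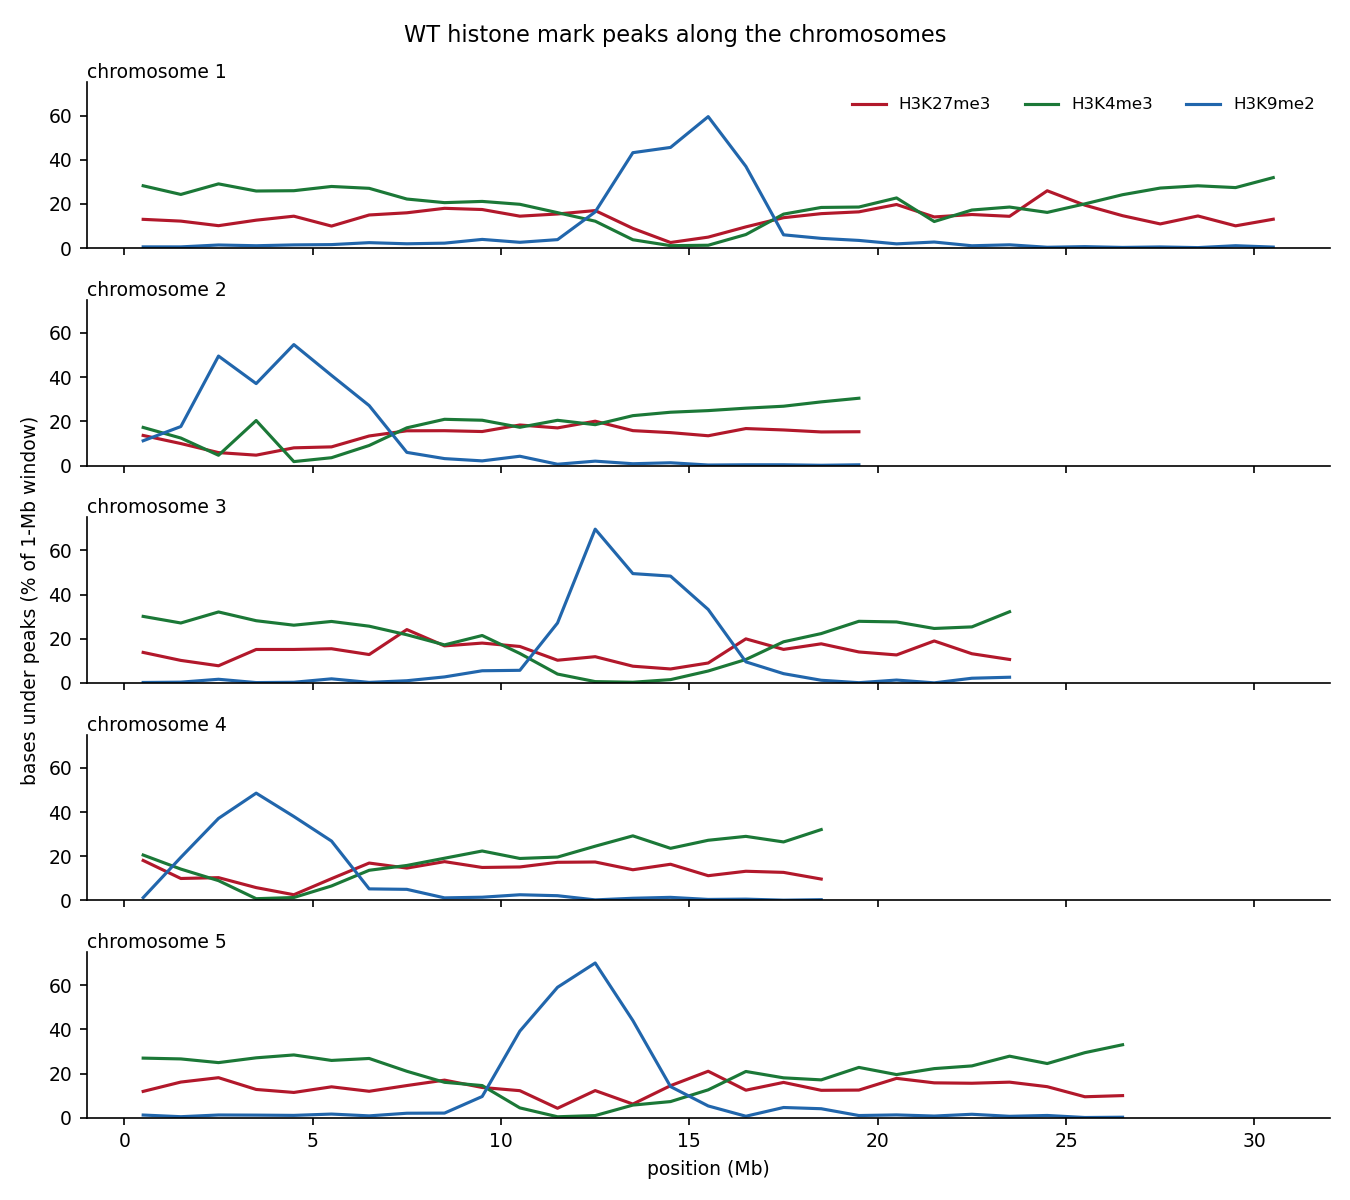
The share of bases under WT peaks is plotted in windows of 1 Mb along each of the 5 chromosomes, with 1 line per mark. H3K9me2 rises to between 48.5% and 70.1% around the centromeres, where H3K4me3 is low apart from the window from 3 to 4 Mb on chromosome 2.

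**Figure D3:**
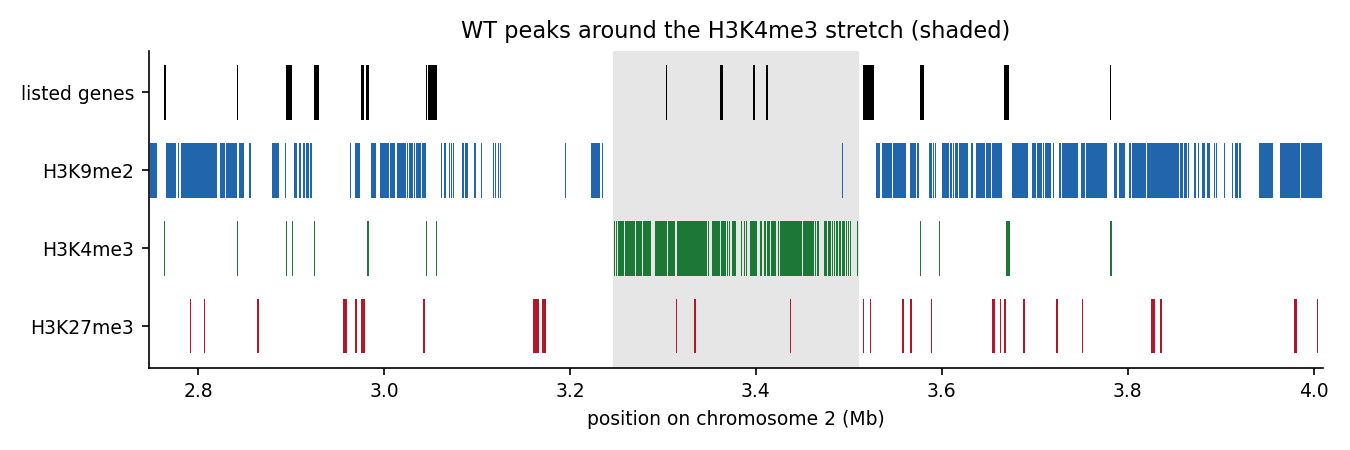
The map shows WT peaks of the 3 marks and the gene loci of the authors' deposited table on chromosome 2, within 500 kb on each side of the shaded stretch from 3247180 to 3509666. H3K4me3 peaks, whose source stays open there, fill 73.8% of the stretch, which holds 4 listed genes.

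The second comparison asked how the marks lie relative to each other. All 3 pairs of WT peak lists shared fewer bases than after circular shifts along the chromosomes. H3K4me3 and H3K9me2 shared 25.1 kb where 1000 shifts gave a mean of 2366 kb (range 1158 to 3233 kb), a ratio of 0.0106. H3K27me3 and H3K4me3 shared 1082 kb against 3111 kb (2920 to 3298 kb), a ratio of 0.348. H3K27me3 and H3K9me2 shared 1136 kb against 1693 kb (1207 to 2046 kb), a ratio of 0.671. The one-sided permutation p, taken in the observed direction, was 0.001 for each pair, the smallest that 1000 shifts can give. The simulated runs covered an excess of shared bases only.

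Marked genes differed in WT expression. Genes with H3K27me3 had a median of 3.95 FPKM (the authors' WT value) against 13.9 FPKM for genes without it, and genes with H3K9me2 had 5.61 against 12.2 FPKM in the authors' deposited table. Genes with H3K4me3 had a median of 14.2 FPKM against 2.78 FPKM for genes without it in the authors' deposited table. In a two-sided permutation test of gene labels the p was 0.0001 for H3K27me3 and H3K4me3, the smallest that 10000 permutations can give, and 0.0011 for H3K9me2. The test runs across genes, which are not independent replicates.

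The third comparison asked whether genes that changed in pold2 carried a given mark in WT. Genes under H3K27me3 were called higher far more often than other genes. By the authors' deposited table, 504 of 3033 genes with H3K27me3 were higher (16.6%, 95% Wilson interval 15.3 to 17.98%), against 681 of 16825 without it (4.05%, 3.76 to 4.36%). The odds ratio was 4.72 (95% interval 4.18 to 5.34), with a Fisher's exact p, two-sided and Benjamini-Hochberg adjusted over 6 tests, of 1.76e-120. Most genes without H3K27me3 carried H3K4me3 alone (15570 genes, 3.55% higher), and 1158 carried none of the marks (10.36% higher). With H3K27me3 alone 18.19% of 1490 genes were higher, and with H3K27me3 and H3K4me3 14.88% of 1505. The odds ratio thus also reflects H3K4me3, and the difference was smaller among genes without H3K4me3. H3K27me3 was carried by 42.5% of the higher genes, 17.0% of the lower genes and 15.3% of all listed genes. Among called changes of at least 2-fold it was carried by 68.2% of the higher and 49.4% of the lower genes. Of the lower genes in the authors' deposited table, 219 lay under H3K27me3 (7.22% against 6.34% without it, odds ratio 1.15, adjusted p = 0.0764 by Fisher's exact test). Compared with unmarked genes drawn at matched mean expression, both directions exceeded the draws, with 504 higher genes against a mean of 148 (middle 95% 125 to 171) and 219 lower genes against 132 (110 to 153). The mean includes the pold2 value, so these draws do not hold WT expression fixed. Among changes of at least 2-fold the odds ratio was 12.5 (9.51 to 16.5) for higher genes and 5.46 (3.49 to 8.55) for lower genes. Genes below 0.501 FPKM in both genotypes are not listed, so marked genes that stayed silent are missing from these shares. That can raise the share called among marked genes, most of all at 2-fold, and its size was not tested.

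Genes with H3K4me3 were called higher less often (4.57% against 14.9%, odds ratio 0.274, adjusted p = 2.89e-75 by Fisher's exact test). They were also called lower less often (6.32% against 7.45%, odds ratio 0.838, adjusted p = 0.0429 by Fisher's exact test), a call that was lost with the better-scoring 50% of each peak list (adjusted p = 0.0595), with at least 200 bp of overlap (0.0584) and without genes that share a locus (0.244). It was further from 1 within the same range of expression (odds ratio 0.403) and for changes of at least 2-fold (0.116). The matched draws gave 2697 higher (2604 to 2792) and 2057 lower genes (1976 to 2139) where 784 and 1084 were observed, drawn from the 2699 genes without H3K4me3. Among the 135 genes with H3K9me2, 17 were higher (12.6%, Wilson interval 8.01 to 19.2%, against 5.92%, odds ratio 2.29, adjusted p = 0.00613 by Fisher's exact test). That call by the exact test was lost with the better-scoring 50% of the peak lists (odds ratio 1.41, adjusted p = 0.540) and within the same range of expression (1.91, adjusted p = 0.102). For lower genes under H3K9me2 the share was 10.4% against 6.44% (odds ratio 1.68, adjusted p = 0.0764 by Fisher's exact test), a ratio that turned to 0.837 with the better-scoring 50% of the peak lists and was called at 10.5 for changes of at least 2-fold. For H3K9me2 the matched draws gave 9.76 higher (4 to 16) and 6.93 lower genes (2 to 12) where 17 and 14 were observed. Intervals cover counting error only, and genes are not independent replicates.

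**Figure D4:**
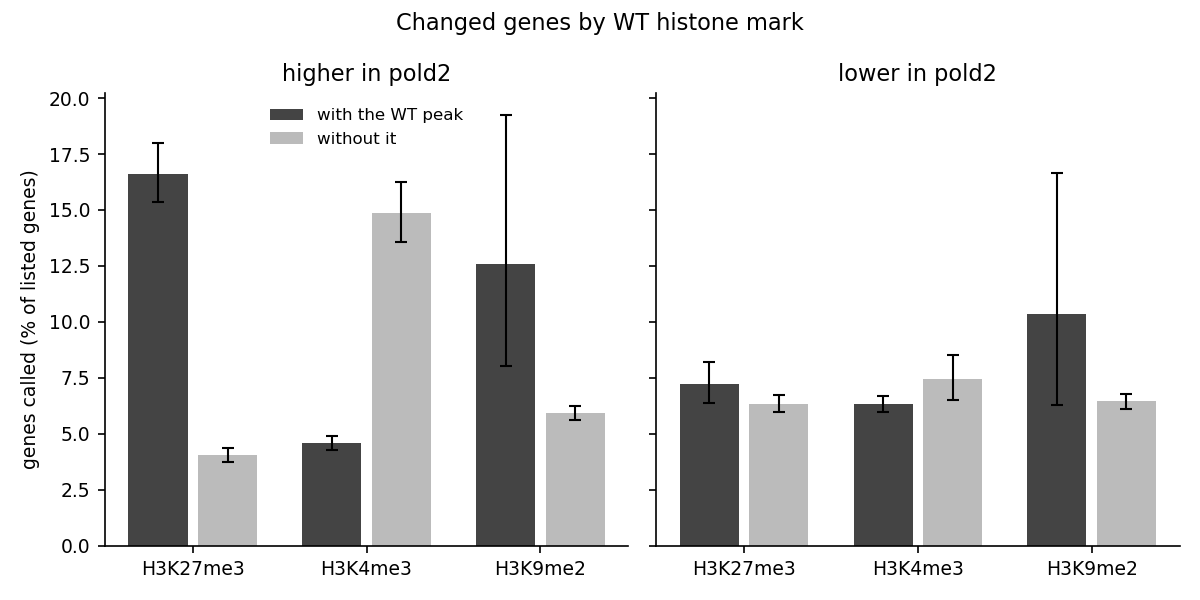
Bars give the share of listed genes called higher (left) or lower (right) in pold2 by the authors' deposited table, for genes with and without a WT peak of each mark, with 95% Wilson intervals. Of the genes with H3K27me3, 16.6% are higher, against 4.05% without it.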

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

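The comparisons of peak scores and of H3K27me3 below were chosen only after the result was seen. The WT peak lists also hold peaks on the organelle genomes, which no comparison used. H3K27me3 had 31 peaks on the mitochondrial genome, H3K4me3 had 58 there and H3K9me2 had 66 on the chloroplast genome. They are flagged only because they lie in data no comparison used and exceed the 3 that a count of 0 allows, which does not show that they are unusual. The mitochondrial H3K4me3 peaks covered 186 kb and the H3K27me3 peaks 92.8 kb, with 25.2 kb shared. Organelle DNA carries no histones, and no control list was compared.

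On chromosome 2, from 3247180 to 3509666, 74 WT H3K4me3 peaks covered 73.8% of 262 kb, against 1.98% and 1.60% of the 500 kb before and after. Promoters of transcribed genes are argued against: 12.2% of these peaks (95% Wilson interval 6.53 to 21.5%) touched a listed gene or the 500 bp around it, against 97.2% of the other nuclear H3K4me3 peaks. Their median score was 202, within the middle range of the mitochondrial H3K4me3 peaks (quartiles 125 and 432) and below that of other nuclear peaks (727 and 2453). Reads of mitochondrial DNA that align to a nuclear copy of it would give such scores. They might also make H3K27me3 peaks denser in the stretch than beside it, which was not seen. H3K27me3 peaks covered 25.3% of the mitochondrial genome up to its last peak but 1.63% of the stretch. Before and after the stretch they covered 5.08% and 6.41%. The 2 marks shared 25.2 kb of mitochondrial bases, so H3K27me3 peaks need not recur where H3K4me3 peaks do, and this cannot decide. No sequence was compared, so the cause stays open. Apart from promoters, no biological explanation was tested.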

How the results depend on the processing

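The settings with a mean of at least 1 FPKM, pseudocount 1, a minimum of 5 FPKM for lists and for transposable element genes, reference pseudogenes as the transposable set, no genes sharing a locus and no genes of the fixed lists were chosen after seeing the data. No paired analysis was possible because the table gives 1 pooled value per genotype. For the same reason leaving out each library, each WT library alone, limma, the set tests camera and fry, and other splits of the samples were not run. Removing the expression minimum was not run either, since the table begins above it. Pseudocounts and median-ratio scaling cannot move the authors' q. Of 74 alternative values of the main results, 52 kept their direction and side of the threshold (or stayed within 1.5 times), 5 gained a call, 16 lost one or shrank and 1 turned.

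The 2470 called genes became 1508 at q under 0.01 (742 higher, 766 lower) and 316 at 2-fold (239 higher, 77 lower), by construction. With a mean of at least 5 FPKM and the adjustment redone over those genes, 681 genes were higher, 38.0% of the 1792 called against 48.0% in the full table. All 1792 were among the 2470. With a mean of at least 1 FPKM 2339 genes were called. With the 85 reference pseudogenes as the transposable set 6 were higher and 1 lower (7.06% against 5.96%, p = 0.643, and 1.18% against 6.49%, p = 0.0440, each by Fisher's exact test, not adjusted), and at 5 FPKM 10 entries were left (odds ratio of both directions 0.785 against 0.555). The 10 lists outside the middle 95% stayed there on the same side with pseudocounts 0.1 and 1. At 5 FPKM 8 did, and flowering activators and anthocyanin genes did not. Medians moved more than percentiles: with pseudocount 1 and at 5 FPKM that of the floral regulators went from 2.80 to 0.71 and 0.50, that of the flowering activators from 0.59 to 0.29 and 0.26, and that of the salicylate and defence genes from 0.48 to 0.32 and 0.25. Jasmonate and wounding genes joined the lists outside with pseudocount 1, and G2/M genes at 5 FPKM. The same pseudocount in both genotypes cannot turn the sign of a gene, but it shrinks large ratios at low values: the log2 ratio of SEP2 went from 6.24 to 5.24 with 0.1 and to 1.27 with 5.

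Genes under peaks numbered 1742 (H3K27me3), 10861 (H3K4me3) and 73 (H3K9me2) with the better-scoring 50% of peaks, and 48 for H3K9me2 with 50% of the locus covered, by construction. The odds ratio of H3K27me3 for lower genes became called with 50% of the locus covered (1.25), at 2-fold (5.46), without the fixed lists (1.19) and in the same expression range (2.17). That of H3K4me3 for lower genes lost its call with the better-scoring 50% (0.881), with 200 bp (0.854) and without shared loci (0.910), but was 0.403 in the same expression range. That of H3K9me2 for higher genes lost its call with the better-scoring 50% (1.41) and in the same expression range (1.91). That of H3K9me2 for lower genes turned to 0.837 with the better-scoring 50% and was called at 2-fold (10.5). At 2-fold all 6 odds ratios were furthest from 1, at 12.5 and 5.46 for H3K27me3, 0.0953 and 0.116 for H3K4me3, and 3.89 and 10.5 for H3K9me2 (higher, then lower). The cause was not tested for these odds ratios. H3K27me3 for higher genes, H3K4me3 for higher genes and the 3 overlaps of peak lists kept their calls in all settings run.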

Other observations

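The test by expression level, the test without shared loci and the matched draws of families below were chosen only after the result was seen, as were the gene families by symbol and the set of ribosomal protein genes. Grouping genes by the letters of their symbol (families of at least 10, 258 tests of shares by Fisher's exact test, two-sided, Benjamini-Hochberg adjusted) gave further groups. Calls follow expression: in the lowest of 10 equal bins of mean FPKM 10.8% of genes were higher and 1.71% lower in the authors' deposited table, and in the highest 3.32% and 18.5%. The families are therefore also set against 10000 draws of other genes matched on mean expression (middle 95% in brackets). Cytochrome P450 genes (CYP) were often higher in the authors' deposited table, 33 of 150 (adjusted p = 1.22e-08, matched draws 5 to 17), with CYP89A9 going from 1.84 to 9.65 FPKM and CYP71A12 from 1.78 to 5.08 FPKM. ABCC transporter genes were higher in 8 of 14 (adjusted p = 2.94e-05, matched draws 0 to 3), among them ABCC3, from 33.6 to 58.4 FPKM in the authors' deposited table. Transcription factor genes of the WRKY family (11 of 52 higher, adjusted p = 0.00754, matched draws 1 to 8) and receptor-like kinase genes of the CRK family (7 of 27 higher, adjusted p = 0.0224, matched draws 0 to 5) were also enriched in the authors' deposited table. WRKY25 went from 4.23 to 8.08 FPKM and CRK30 from 5.32 to 9.70 FPKM in the authors' deposited table.

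Among lower genes, histone H2A genes (HTA) stood out in the authors' deposited table, with 7 of 10 lower (adjusted p = 3.04e-05, matched draws 0 to 4), for example HTA13, from 102 to 63.5 FPKM, which shares its locus with another gene. Auxin-responsive SAUR genes were lower in 6 of 13 (adjusted p = 0.00373, matched draws 0 to 2), with SAUR19 going from 3.59 to 1.31 FPKM in the authors' deposited table, and members can share reads. Of 47 genes with symbols beginning with RPL or RPS, 42 have a ribosomal protein among their reference synonyms, and the other 5 were left out. Of these 42, which mix cytosolic, plastid and mitochondrial ribosomal proteins, 21 were lower and 0 higher in the authors' deposited table, against a mean of 7.84 lower genes in the matched draws (3 to 13, highest 18). In the authors' deposited table RPL21C fell from 267 to 188 FPKM.

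Genes with a WT H3K27me3 peak were more often higher in pold2. Low mean FPKM over both genotypes is argued against as the whole cause. Over 10 equal bins of it the share higher among marked genes was 2.63 to 5.75 times that among unmarked genes. That mean includes the pold2 value, so a gene that rose moves to a higher bin. Low expression in WT alone was therefore not tested. Locus length is argued against too, since the lowest lower bound of the odds ratio over 5 bins of length was 2.47, and so are shared loci, without which the odds ratio was 4.41 (3.89 to 4.997). Loci covered by the mark over at least 50% of their length were higher in 18.4% (16.9 to 20.06%), against 10.6% (8.505 to 13.1%) of loci covered less. Such a difference was predicted from a link to the mark over the gene itself. The loci covered over at least 50% were also lower in 7.76%, against 6.30% of all other listed genes (odds ratio 1.25). The split by coverage was not matched on expression or locus length, so it does not settle such a link. Marked genes may also follow a change in developmental stage, since 8 of 16 floral regulators were higher, and this was not tested. A lack of H3K4me3 may be part of the pattern. Genes with H3K27me3 alone were higher in 18.19%, against 10.36% of genes with none of the marks. Whether H3K27me3 itself differs in pold2 was not analysed here.

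The photosynthesis genes were lower in pold2. Whether a general fall of highly expressed genes is the cause cannot be decided. The list lay at percentile 0.02 of lists matched on expression (middle 95% of medians -0.24 to -0.03). That shows only a fall beyond that of genes in the same bins, and expression is not equal within the highest bin. Over 10 equal bins of mean FPKM, the highest ran from 74.1 to 16677 FPKM and had the largest share of lower genes (18.5%). LHCA1 was at 4782 FPKM in WT. The 42 ribosomal protein genes had a median log2 ratio of -0.30 (quartiles -0.34 and -0.17) against -0.33 (quartiles -0.44 and -0.24) for photosynthesis genes. A loss specific to photosynthesis and one shared with other abundant transcripts therefore cannot be told apart, because these ranges overlap. The pold2 genotype stays open as a biological explanation.

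Neighbouring genes rose together more often than chance placement gives. There were 133 adjacent pairs of listed genes, on different loci, both higher in the authors' deposited table, against a mean of 65.5 in 10000 permutations (middle 95% 51 to 81, highest 95). Among pairs with no WT H3K27me3 peak on either gene, 44 were both higher, against 21.9 (13 to 31, highest 40), so H3K27me3 domains that span neighbours may be part of the pattern but did not account for all of it. Duplicated neighbours and reads that run from one gene into the next were not tested.

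The deposited log2 ratio of GLT1 (AT5G53460) is 0.33 in the authors' deposited table, whereas its FPKM values of 257 and 343 give 0.41. AT3G45851 was listed at 0 in WT and at 8095 FPKM in pold2, with q = 0.511 (it shares its locus with another gene), and AT3G42090.1 at 1573 FPKM in WT and 0 in pold2, with q = 0.145, in the authors' deposited table.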
